A study of Arabidopsis thaliana with 2 samples.

How the data were processed

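ChIP-seq was performed on inflorescence tissue of Arabidopsis thaliana ap1 cal1 plants carrying 35S:LFY-GR, with 1 library precipitated with a polyclonal serum against LFY and 1 input library. Chromatin was sonicated to fragments of about 200 to 500 bp, per the labels' protocols. The deposited file is 1 list of peaks. Per the file headers, peaks called for the LFY library against a contrast were annotated with HOMER annotatePeaks.pl using its tair10 set. Per the submitters' processing notes, MACS 1.4, HOMER, FastQC and the TAIR10 build were used. The aligner, the peak calling threshold and the treatment of duplicate reads are not given in the sources used here, nor is whether libraries were pooled. The header does not name the contrast library, and the input was the only other library used here.

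The unit of the deposited values is the peak score that the authors' caller assigned to each peak. Its lowest value of 50.03 and its range fit a score of minus 10 times the logarithm of p, which MACS 1.4 writes by default, but no header states the scale. It was used only to rank and filter peaks within the list. The file also gives start and end positions and the distance from the peak centre to the nearest TSS in bp. Polyclonal serum also recognises LFY that is not fused to GR, so a peak does not tell fusion protein from native protein. A caller that compares with input removes regions that are high in both libraries, while regions that are open or highly transcribed can still be enriched by precipitation.

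Read counts, coverage and the input signal were not used here, so depth, fold enrichment and the precision of a single peak are unknown. All 529 peaks lay on the 5 nuclear chromosomes and all entered the analysis. Shares carry 95% Wilson intervals, and a count of 0 is given with the share that 3 counts allow. Both cover counting error only.

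A gene had a peak when the authors' annotation named it as the nearest promoter. Gene symbols and gene order were taken from a RefSeq gene table of assembly TAIR10.1, which matched 499 of the 512 loci. Because that assembly carries another name than the build of the peaks, its coordinates were not used. All positions are those of the peak list (TAIR10). Before the data were examined, 13 gene lists with 259 distinct loci were fixed, 3 of them as controls (photosynthesis, root development and housekeeping), and all 259 loci were in the table. The lists share 9 loci. Photosynthesis, root, and anther and ovule genes stood for other tissues and later stages. Each list was compared with all other nuclear genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 13 lists and a threshold of 0.05. The table holds classes of genes that the authors' annotation set may lack, which lowers the background rate, so the comparison was repeated with 27444 protein-coding genes. On simulated data with 37899 genes and as many genes with a peak as observed, 2% of 200 runs with no enriched list gave a call. When 20% of the members of a list of 17 or 29 genes were given a peak, the list was called in 100% of runs. Smaller shares, and enriched lists of other sizes, were not simulated.

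The genes named in the text follow a rule fixed beforehand. They are the genes nearest to the 20 highest-scoring peaks and every list member with a peak. List members inside which a peak was annotated are named as well. Of the list members without a peak, those named were chosen after their values were seen, as were genes named as neighbours and the other genes of the closing observations. The planned random placement of peaks, the motif and 6-mer tests at peak centres, and the score of peaks with and without the LFY core motif need a genome sequence of the build, which was not used here. In their place, annotation classes and distances are described with intervals and compared between the 265 higher-scoring and 264 lower-scoring peaks (Fisher's exact test), upstream and downstream positions by an exact binomial test, and scores by a permutation test of mean rank with 100000 resamples. These tests were chosen after the data were seen. Alternatives were the 265 and the 133 highest-scoring peaks, limits on TSS distance and on width, and other ways to assign genes and to set the background. Calculations used Python 3.11.15, SciPy 1.17.1, NumPy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.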

Results

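Binding of LEAFY (LFY), the transcription factor that directs the switch from shoot to flower in Arabidopsis thaliana, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in inflorescence tissue. The plants were ap1 cal1 mutants, which carry mutations in the related floral regulators APETALA1 (AP1) and CAULIFLOWER (CAL). They carried LFY fused to the glucocorticoid receptor hormone-binding domain (LFY-GR) under the constitutive 35S promoter, a fusion that enters the nucleus when dexamethasone is added. Tissue was collected 4 h after treatment with 10 µM dexamethasone from plants grown for 4 weeks. There was 1 library made with rabbit serum raised against LFY and 1 input library made without antibody. With no replicate of either, no value below has an error between libraries, and each test describes how the peaks of this list lie relative to genes. The sequencing depth of the libraries is unknown here, because the list holds peaks and scores but no read counts. Intervals on shares cover counting error only.

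The first question was where the peaks lay in this tissue, collected after dexamethasone treatment. Without an untreated library, no peak can be tied to activation of the fusion. The list held 529 peaks, with 138 on chromosome 1, 76 on chromosome 2, 106 on chromosome 3, 90 on chromosome 4 and 119 on chromosome 5. The peaks were nearest to 512 different genes. Peak width had a median of 1168 bp and ranged from 612 to 5326 bp. The score, which is the peak caller's own value as the authors deposited it, ranged from 50.0 to 2952.3 with a median of 133. The longest stretch without a peak ranged from 2.84 Mb on chromosome 4 to 3.92 Mb on chromosome 2, and the median gap between peaks ranged from 88.8 to 122 kb over the 5 chromosomes.

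**Figure D1:**
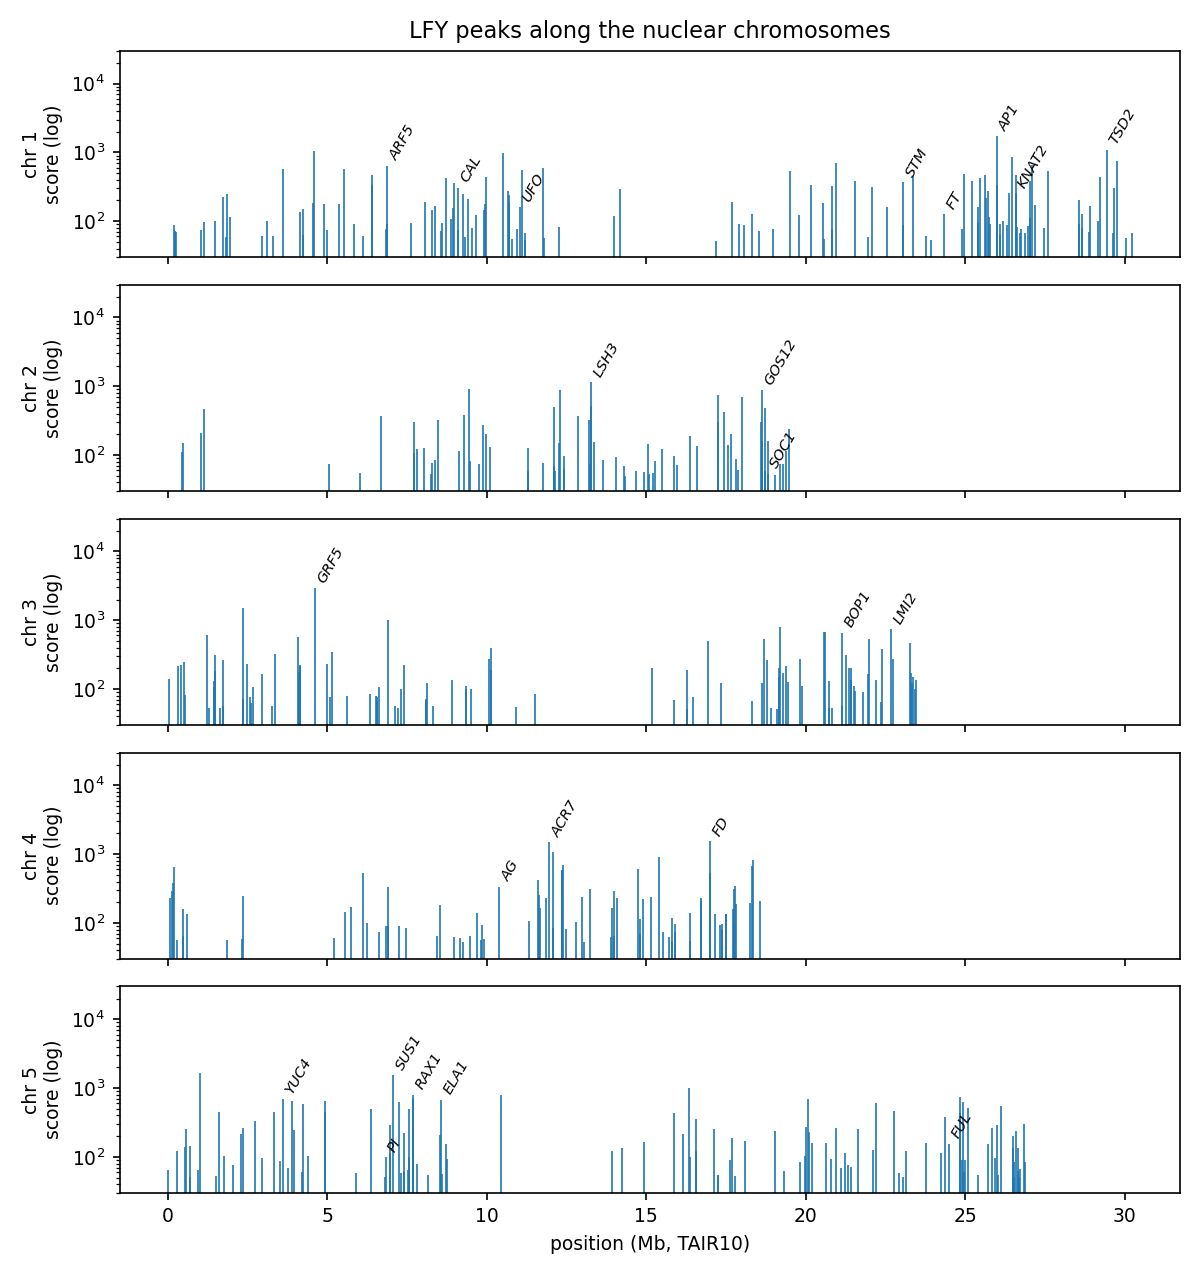
LFY peaks along chromosomes 1 to 5, with position in Mb (TAIR10) on the horizontal axis and the authors' peak score on a logarithmic vertical axis. Each line is 1 peak, and gene symbols mark the strongest peak assigned, by nearest promoter, to each of selected genes named in the text. The tallest line, at GRF5 on chromosome 3, has a score of 2952.3.

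The strongest peak, with a score of 2952.3, lay on chromosome 3 from 4605469 to 4607797 (TAIR10), centred 1750 bp upstream of GROWTH-REGULATING FACTOR 5 (GRF5, AT3G13960), a transcription factor gene that promotes cell proliferation in leaves. The next peak by score covered the AP1 promoter (AT1G69120, chromosome 1 from 25985943 to 25987325, score 1710.2, centre 321 bp upstream of the TSS). The third peak by score, 1643.9, was intergenic on chromosome 5 from 1021260 to 1023294 and was assigned to AT5G03837. That locus is absent from the gene table, and the next locus code in the table is that of TFL1, the inflorescence identity gene. The fourth, 1549.4, lay 2133 bp upstream of FD (AT4G35900, chromosome 4 from 17001649 to 17003276), which encodes the bZIP partner of the florigen FT. The fifth, 1540.3, lay 3876 bp upstream of SUS1 (AT5G20830), which encodes a sucrose synthase.

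The other genes among the 20 with the strongest peaks came from several functional classes. LSH3 (AT2G31160), a boundary gene of the shoot apex, had a peak with a score of 1137.0 centred 1090 bp upstream. ACR7, which encodes an ACT domain protein, had a peak centred in its 3' UTR with a score of 1488.3. Genes of sugar and trehalose metabolism were a trehalose-phosphate phosphatase gene (AT2G22190, score 928.7, 273 bp upstream) and TPS8 (score 846.1, 826 bp upstream). TSD2, which encodes a putative pectin methyltransferase, had a score of 1100.0. IQD22 had a score of 1074.2, with the peak at the transcription termination site of AT4G23050. AT5G40810 (a cytochrome c1 gene, 1001.5), GOS12 (a Golgi SNARE gene, 887.3) and CYP96A9 (a cytochrome P450 gene, 835.4) were also among the 20. The peak at GOS12 lay 4448 bp downstream of its TSS, and the protein-coding genes on either side of GOS12 in the gene order are SAUR36 and FILAMENTOUS FLOWER (FIL, also AFO), a gene of lateral organ polarity. Of the 20 genes, 8 carried only the description hypothetical protein in the authors' annotation, which included LSH3. They were AT5G03837, AT3G07350, LSH3, AT1G13360, AT3G19870, AT1G30016, AT4G31875 and AT2G28671, with scores between 876.6 and 1643.9. By position, 10 of the 20 strongest peaks were intergenic, 8 were in promoters and 2 were at the 3' end of a gene.

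The next question was how the peaks were placed relative to genes. Promoters held 214 of 529 peaks (40.5%, 95% Wilson interval 36.4 to 44.7). Intergenic sequence held 121 (22.9%, 19.5 to 26.6), and the region around a transcription termination site held 75 (14.2%, 11.5 to 17.4). Exons held 66 (12.5%, 9.93 to 15.6), introns 38 (7.18%, 5.28 to 9.71), 5' UTRs 8 (1.51%, 0.768 to 2.96) and 3' UTRs 7 (1.32%, 0.642 to 2.71). Of all peaks, 56.5% (299, interval 52.3 to 60.7) were centred within 1 kb of the nearest TSS and 90.0% (476, interval 87.1 to 92.3) within 3 kb. Peaks were upstream of the nearest TSS in 302 cases and downstream in 227 (exact two-sided binomial test against an even split, adjusted p = 0.00255 over 2 tests of distance).

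Strong and weak peaks differed in placement. Among the 265 higher-scoring peaks, 27.9% were intergenic, against 17.8% of the 264 lower-scoring peaks (Fisher's exact test, two-sided, adjusted p = 0.0244 over 7 classes). Exons held 7.55% of the higher-scoring and 17.4% of the lower-scoring peaks (Fisher's exact test, adjusted p = 0.00415). The shares in promoters, 38.5% and 42.4%, did not pass Fisher's exact test (adjusted p = 0.63), and neither did those of the remaining classes (adjusted p between 0.63 and 1). Peaks centred within 1 kb of a TSS made up 52.1% of the higher-scoring and 61.0% of the lower-scoring peaks (Fisher's exact test, adjusted p = 0.0437). Within 3 kb the shares were close, 90.2% and 89.8%, and were not tested. The median score was 179 for intergenic peaks and 123 for all others (permutation test of mean rank, two-sided, 100000 resamples, adjusted p = 0.0026 over 2 tests of score). The score test, the intergenic share and the share within 1 kb draw on the same peaks and are not independent results. How often such positions would be met by chance was not tested, since no genome sequence was used here.

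**Figure D2:**
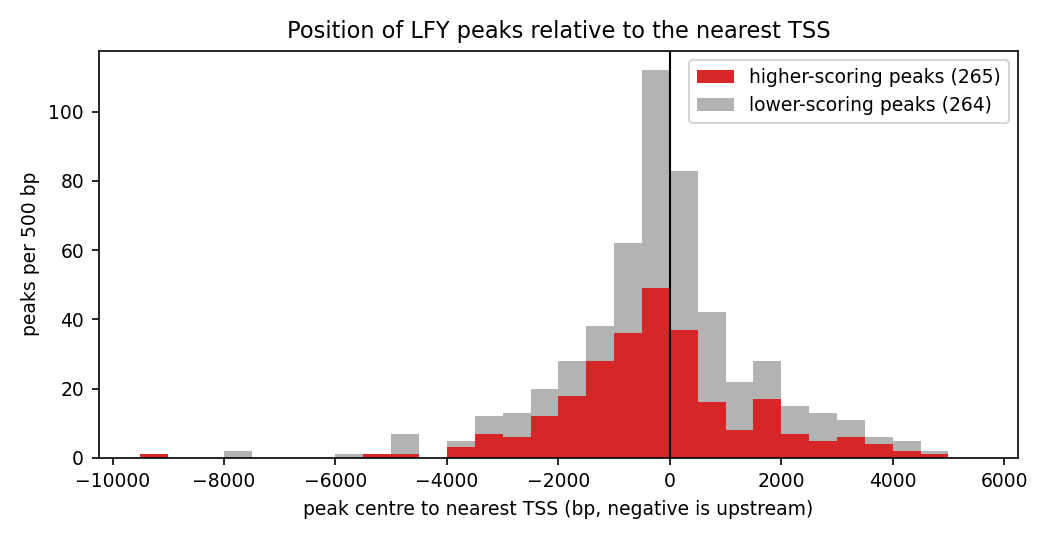
Number of LFY peaks per 500 bp of distance between the peak centre and the nearest TSS (bp, negative values upstream), stacked for the 265 higher-scoring peaks (red) and the 264 lower-scoring peaks (grey). Of all 529 peaks, 302 lay upstream and 227 downstream of the TSS.

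Known LFY targets and floral regulators were next to peaks more often than genes in general. Of 37899 nuclear genes in the gene table, 499 (1.32%) were nearest to a peak, against 6 of 11 genes reported before as LFY targets (54.5%, odds ratio 90.9, 95% interval 23 to 378, Fisher's exact test with Benjamini-Hochberg adjustment over 13 lists, adjusted p = 9.6e-09). These were AP1, CAL, AGAMOUS (AG), LMI2, RAX1 and ELA1. AG, the organ identity gene of stamens and carpels, had its peak in intron 2 (score 336.8, chromosome 4 from 10385583 to 10387157), 3514 bp downstream of the TSS. LMI2, a MYB gene of floral meristem identity, had a promoter peak (score 746.9, 677 bp upstream). RAX1, a MYB gene of axillary meristems, had a promoter peak (685.4) and a second in exon 3 (802.3). ELA1, a cytochrome P450 gene of gibberellin metabolism, had a peak 61 bp downstream of its TSS (675.2). Of the list, 9 genes are members of other lists as well. AP3, SEP3, TFL1, LMI1 and ARR7 were not named as the nearest gene of any peak, and SEP3 was the protein-coding neighbour of a gene that was. Neighbours were looked up only for loci in the gene table. The 13 loci absent from it, among them AT5G03837, were given none, so TFL1 was not checked as a neighbour of AT5G03837.

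AP1 and CAL, the genes mutated in these plants, each had 2 peaks. At AP1 a second peak was centred in intron 4 (score 336.6, chromosome 1 from 25982728 to 25985532), although its nearest promoter was that of the neighbouring pseudogene AT1G69110. At CAL the stronger peak was centred in intron 4 (score 307.1, chromosome 1 from 9100261 to 9103138) and a weaker one in the promoter (75.03, 327 bp upstream), with a gap of 142 bp between them. Of the 17 genes of floral organ identity, 5 had a peak (29.4%, odds ratio 31.5, interval 8.66 to 96.6, adjusted p = 6.8e-06 by Fisher's exact test). Besides AP1 and AG these were SEP4 (470.9, intron 1), UFO, an F-box gene that acts with LFY (158.4), and PISTILLATA (PI, 98.2, promoter). The remaining 12, among them SEP1, SEP2, SEP3, AP2 and AP3, had none.

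Among 29 genes of flowering time and floral meristem identity, 9 had a peak (31.0%, odds ratio 34.3, interval 13.7 to 79.3, adjusted p = 1.1e-09 by Fisher's exact test). FD had the strongest at 1549.4, and a second peak at its 3' end (533.0) was assigned to the next gene. The FD paralogue FDP had 2 peaks (304.6 and 105.8), 451 bp apart. TEM1, a repressor of FT, had a score of 352.8, and SPL5 and SPL4, SBP-box genes that promote flowering, had 340.5 and 121.6 with centres 52 bp downstream and 77 bp upstream of the TSS. FUL had a score of 155.4, FT 125.1 and SOC1 53.7, the last 2 centred 4020 bp downstream and 3588 bp upstream of their TSS. Of the 20 members without a nearest peak, LFY itself contained one, centred in its intron 2 and assigned to AT5G61865 (chromosome 5 from 24843810 to 24847841, score 752.4). That peak was 4032 bp wide, and only 1 peak in the list was wider. The 35S:LFY-GR transgene, present in both libraries, carries LFY sequence too.

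Of 28 shoot meristem and boundary genes, 8 had a peak (28.6%, odds ratio 30.4, interval 11.5 to 72.6, adjusted p = 9.6e-09 by Fisher's exact test). The homeobox gene STM, which maintains the meristem, had a peak at its TSS (367.4) and one 4846 bp upstream (88.5). KNAT2 had a peak in intron 3 (253.1) and a second in the same intron assigned to another gene (464.6). The boundary genes BOP1 (656.2 and 56.5, 432 bp apart), BOP2 (300.8), CUC3 (128.3 and 78.7) and LSH3 (1137.0 and 524.8) had peaks, as did ATH1 (97.7 and 74.9) and RAX1. KNAT6 contained a peak in its intron 3 that was assigned to the neighbouring gene (143.8). No peak was assigned to WUS, CLV1, CLV3, CUC1 or CUC2. Of 22 genes of organ polarity and growth, 3 had a peak (13.6%, odds ratio 11.9, interval 2.25 to 40.6, adjusted p = 0.00613 by Fisher's exact test). They were AIL6 (448.8, intron 3), ANT (158.2 and 97.5) and FIL (54.3, promoter).

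Peaks were also assigned to hormone genes. In the auxin list 5 of 29 genes had one (17.2%, odds ratio 15.8, interval 4.68 to 42.4, adjusted p = 9.2e-05 by Fisher's exact test). These were the biosynthesis genes YUC4 (696.8) and YUC1 (62.3), the response factor genes ARF5 (638.9, 3982 bp upstream) and ARF6 (237.7), and IAA17 (98.4). A peak at the 3' end of the auxin carrier gene AUX1 (73.0) was assigned to the gene beside it. In the gibberellin list 3 of 23 did (13.0%, odds ratio 11.3, interval 2.14 to 38.3, adjusted p = 0.00613 by Fisher's exact test), namely ELA1, the biosynthesis gene GA20OX1 (241.7) and the catabolic gene GA2OX4 (192.5). ELA1 is also among the reported LFY targets, so the gibberellin call is not independent of that list. In the cytokinin list 3 of 25 did (12%, odds ratio 10.3, interval 1.96 to 34.4, adjusted p = 0.00684 by Fisher's exact test), namely the biosynthesis gene IPT5 (489.8), the response regulator gene ARR3 (313.8) and the degradation gene CKX3 (50.4). When only peaks within 1 kb of a TSS were counted, 0 auxin, 0 cytokinin and 1 gibberellin gene had one, and none of these lists passed the test (adjusted p = 1, 1 and 0.264 by Fisher's exact test).

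Control lists were treated in the same way. None of 20 photosynthesis genes had a peak, which allows a share of up to 15.0%, and TUB6 (248.8, promoter) was the 1 of 15 housekeeping genes that did (6.67%, adjusted p = 0.234 by Fisher's exact test). Of 17 root development genes, TMO5 (109.1) and GL2 (56.6) had a peak (11.8%, odds ratio 10, interval 1.11 to 43.3, adjusted p = 0.0298 by Fisher's exact test). The call was lost among the 265 higher-scoring peaks (0 members, adjusted p = 1 by Fisher's exact test), with peaks within 3 kb of a TSS (1 member, adjusted p = 0.24), with peaks within 1 kb (1 member, adjusted p = 0.228) and against protein-coding genes only (the same 2 members, odds ratio 7.53, adjusted p = 0.0502). With neighbouring genes counted, 6 of the 17 had a peak (odds ratio 14.1, adjusted p = 5.1e-05 by Fisher's exact test). With 2 members in the full comparison, 1 gene can end the call. The root odds ratio of 10 is near those of the polarity (11.9), gibberellin (11.3) and cytokinin (10.3) lists. Its interval (1.11 to 43.3) overlaps those of all other passing lists as well. The intervals therefore set no passing list apart from this control. No peak was assigned to any of 20 immune signalling genes or of 12 anther and ovule genes, which allow shares of up to 15.0% and 25%. In all, 9 of the 13 lists passed at an adjusted p under 0.05, and 8 did against protein-coding genes only.

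Peaks of list genes also scored higher. The 46 peaks assigned to the 37 members with a peak of the 10 developmental, hormone and immune lists had a median score of 247, and the other 483 peaks had a median of 129 (permutation test of mean rank, two-sided, 100000 resamples, adjusted p = 0.0026). The test treated each peak as a separate unit, although 9 of these members had 2 peaks. The lists also include genes chosen because they were reported before as LFY targets.

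**Figure D3:**
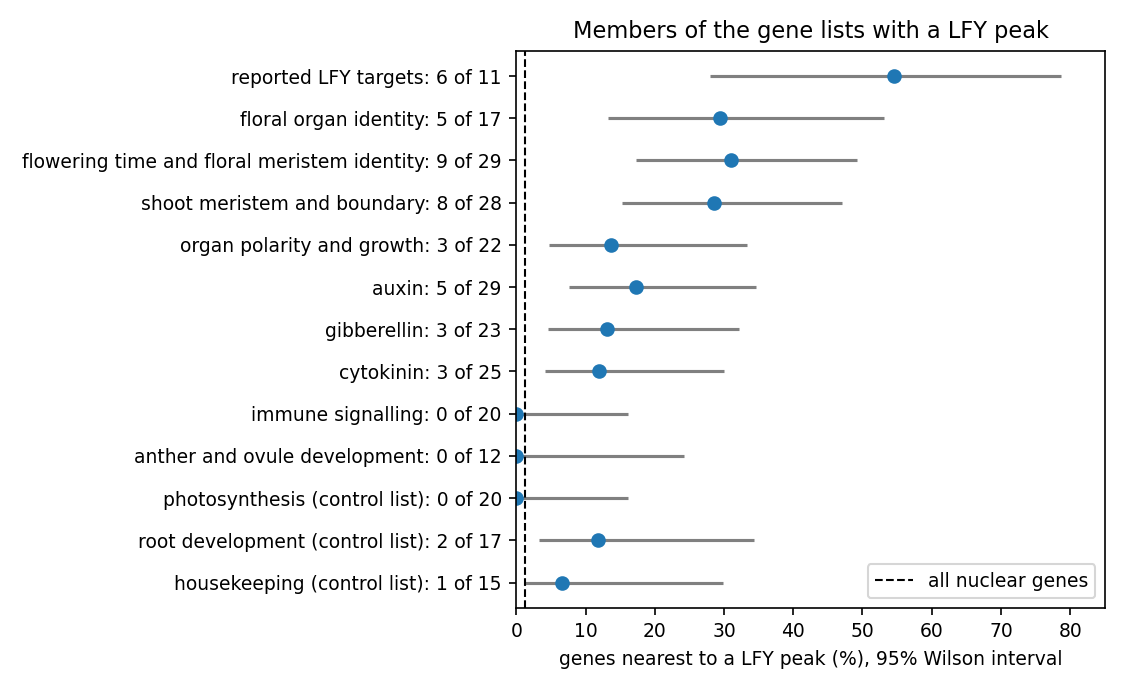
Share of the members of each gene list that were nearest to a LFY peak (%, points) with 95% Wilson intervals (lines), and the share of all nuclear genes (1.32%, dashed line). The reported LFY targets stand highest at 54.5%, and the immune, anther and ovule, and photosynthesis lists stand at 0.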

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

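The comparison of the housekeeping list with all genes was planned. All other tests in this part were chosen after the data were seen, and all but that of peaks within 1 kb for the 10 lists together after the result they measure was seen. A column that the comparisons did not use places 5 of the 529 peaks (0.945%, 95% Wilson interval 0.404 to 2.19) inside annotated transposons; how many would lie there by chance was not tested. Of these, 3 were in helitrons, at MSL10 (score 658.8), AT1G66920 (492.8) and KP1 (52.0), and 2 were in DNA transposons, at AT1G23700 (165.8) and AT1G12200 (135.2).

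Members of the 10 developmental, hormone and immune lists had a peak more often than other genes (37 of 207, odds ratio 17.5, interval 11.8 to 25.5). Genes beside long intergenic regions are named as nearest promoter more often, and this explanation stays open. With only peaks within 1 kb of the TSS the odds ratio of the 10 lists together was 11.4 and its lower bound 6.3. The difference of the 10 lists together therefore did not rest on distant peaks alone. For the 3 hormone lists the odds ratio fell to 1.7 (interval 0.0424 to 9.85), from 12.7 (6.03 to 24.5) at any distance, and these intervals overlap. A limit of 1 kb keeps genes with long flanks, and the length of the flanks was not measured, so the test cannot decide. Enrichment of highly transcribed chromatin whatever the antibody stays open: the photosynthesis and housekeeping lists had a peak at 1 of 35 genes (Fisher's exact test against the 10 lists, p = 0.0224), but transcription in this tissue was not measured here, and the housekeeping list alone (odds ratio against all genes 5.36, interval 0.127 to 35.4) is too small to decide. An affinity of the loci of developmental regulators of any organ cannot be told apart from LFY binding, since the root list of 17 genes is too small (odds ratio of the 10 lists against it 1.63, interval 0.354 to 15.3, p = 0.7435 by Fisher's exact test). Binding by LFY, which the design names, also stays open, as untested without a second library or a serum control.

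The peak over LFY itself was 4032 bp wide, wider than all 50 peaks of neighbouring score rank (median 1375 bp, widest 3281 bp), and was centred inside the gene. This width is what reads from the 35S:LFY-GR transgene, which carries LFY sequence, may give. The input library holds the same transgene, and the list gives no read profile that would separate exons from introns. Binding of LFY to its own gene therefore stays open as well, as untested. A separate peak (chromosome 5 from 24841624 to 24842730, score 429.2) ended before the LFY peak began. It was assigned to GUT1 (AT5G61840), centred 237 bp upstream of that gene's TSS. Whether its sequence is also part of the transgene was not determined.

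Of the 512 genes to which peaks were assigned, 17 had 2 and none had more, and 9 of these 17 belonged to the 10 lists (52.9%, against 28 of 495 genes with 1 peak, 5.66%; Fisher's exact test, odds ratio 18.5, interval 5.84 to 59.8, p = 3.2e-07). They were CAL, STM, CUC3, FDP, LSH3, BOP1, ATH1, ANT and RAX1. Room for a second peak in long intergenic regions stays open. Among genes whose peaks all lay within 3 kb of the TSS, 5 of 11 with 2 peaks and 23 of 449 with 1 peak were list members (p = 2.1e-04 by Fisher's exact test). That limit keeps genes with long flanks, and the length of the flanks was not measured, so the test cannot decide. A split of 1 broad region by the caller stays open. List members were frequent both among the 10 genes with peaks over 500 bp apart (6 members, p = 1.0e-05 by Fisher's exact test) and among the 7 with closer peaks (3 members, p = 0.006323 by Fisher's exact test), and membership does not measure splitting. The gaps were 3824 bp at STM, 3300 at ANT, 2929 at LSH3, 1148 at ATH1, 957 at RAX1 and 808 at CUC3. At CAL, BOP1 and FDP they were 142, 432 and 451 bp. The list gives no signal between 2 peaks. More than 1 LFY-bound element at these genes stays open too, as untested.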

How the results depend on the processing

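Alternatives within 1 kb, with neighbouring or annotated genes with protein-coding genes and with the strongest peak of each gene were added after the data were seen. Stricter score limits left 265 and 133 peaks by construction. Among the 265 the intergenic share was 27.9%, the exonic share 7.55% and the share within 1 kb of a TSS 52.1%, each outside the interval of the full list. The 265 are part of that list, so its interval is no test of a difference. Their own interval within 1 kb, 46.1 to 58.0, holds the full-list share of 56.5%. The cause was not tested. The 5 lists of reported targets, floral organ identity, flowering time, meristem and polarity genes passed under every alternative run. Their odds ratios were lower with neighbouring genes included (5.73 to 45.2) than in the full comparison. With peaks within 1 kb only, 5 lists passed in place of 9, where 291 genes had a peak: auxin and cytokinin had 0 members and gibberellin had 1. At so few genes with a peak, a count of 0 shows no reversal. Over the alternatives, adjusted p by Fisher's exact test ranged from 2.3e-06 to 1 for auxin, from 2.9e-04 to 0.264 for gibberellin and from 0.00592 to 1 for cytokinin. The cytokinin list kept 3 members but missed the threshold when neighbouring genes were counted, which raised the genes with a peak to 1418 (odds ratio 3.51, adjusted p = 0.0942 by Fisher's exact test). The root control list had 0 members among the 265 highest-scoring peaks, 1 within 3 kb, 1 within 1 kb and 2 against protein-coding genes only (adjusted p = 1, 0.24, 0.228 and 0.0502 by Fisher's exact test), but 6 of 17 with neighbouring genes (adjusted p = 5.1e-05). The 4 lists that did not pass did so under no alternative. Keeping the strongest peak of each gene raised the score difference of list genes by construction, because many list genes had 2 peaks, and is no check of it. Not run, for want of a genome sequence and coordinates of the build, were random placement, GC-matched windows, own annotation of peak centres, TSS of protein-coding genes only, gene windows of 3 kb upstream and 1 kb downstream, all motif and 6-mer alternatives, and the score by motif. No paired analysis was possible because there is 1 library per group. Depth is unknown, so weak peaks cannot be weighed against sampling noise.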

Other observations

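The tests in this part were chosen after the data were seen. Beyond the fixed lists, words in the names of 27444 protein-coding genes were tested for peaks (1358 words shared by 8 to 400 genes, two-sided Fisher's exact test, Benjamini-Hochberg adjustment), and 4 words passed. "Agamous" marked MADS-box genes, of which 9 of 99 had a peak (Fisher's exact test, adjusted p = 0.0204). The call rests on AG, since the near-identical group "agamous-like", which lacks it, did not pass (8 of 98, adjusted p = 0.0734 by Fisher's exact test). Besides the genes of the fixed lists these were MAF4 (score 295.2, promoter), a relative of the flowering repressor FLC, AGL6 (162.9, in an intron) and AGL44 (55.4, promoter). "Homeobox" marked 8 of 67 genes (Fisher's exact test, adjusted p = 0.0124), among them PRS (151.5), which acts in the margins of lateral organs, and KNAT4 (88.0). "Floral" (5 of 13, adjusted p = 0.00247 by Fisher's exact test) held AP1, FIL, PI, SPL4 and UFO, and "mads" (4 of 11, adjusted p = 0.0124) held CAL, MAF4, SEP4 and SOC1, most of them members of the fixed lists.

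Other groups of names did not pass the correction. The flavonol group had 3 of 10 genes with a peak (adjusted p = 0.0847 by Fisher's exact test), namely MYB111 (275.9, promoter) and MYB12 (242.3), which regulate flavonol synthesis, and FLS6 (190.4). The WIP zinc finger group had 3 of 10 as well (adjusted p = 0.0847 by Fisher's exact test), namely NTT (202.8), WIP4 (100.4) and WIP5 (77.6). Aquaporin genes of the plasma membrane had 3 of 13 (adjusted p = 0.15 by Fisher's exact test), with PIP1;4 (646.0) the strongest. A second growth-regulating factor gene, GRF3, had a promoter peak with a score of 82.7, below that of GRF5, and a second sucrose synthase gene, SUS4, had one of 200.4.

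Among the genes nearest to peaks were 4 microRNA genes, a group that was not tested. MIR172D, whose product acts on AP2-like genes, had a score of 684.8 with the centre 653 bp downstream of its TSS, MIR319A, whose product acts on TCP genes, 585.6 at 562 bp upstream, MIR169C 440.2 at 603 bp upstream and MIR866A 212.7 at 1157 bp upstream. The third strongest peak was assigned to AT5G03837, a locus that is absent from the gene table. Locus codes are numbered along the chromosome, and the next code in the table is AT5G03840, TFL1, the inflorescence identity gene. TFL1 was not the nearest promoter of any peak.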
